A study of Homo sapiens with 12 samples.

How the data were processed

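Poly(A) RNA of HEPM cells, a human line of embryonic palatal mesenchyme, was sequenced 6 h after transfection with a plasmid for MSX1, either wild type (WT) or with a single arginine changed. Per the labels, 4 plasmids were used (WT, R157S, R157K and R157F), with 3 libraries each, 12 in all. Per the labels' protocols, cells were grown in α-MEM with fetal bovine serum, RNA was taken with TRIzol and libraries were made with the Illumina Stranded mRNA Prep kit. The labels hold no empty-vector or untransfected group, and such cells were not analysed here. Groups and replicate numbers were taken from the labels, and every column of values matched 1 sample.

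The deposited file is a single table of TPM, transcript abundance relative to the library total, per gene and library, made by the authors. RSEM is named in the submitters' processing notes, without a version, and the aligner, genome build and annotation are not given in the sources used here. The table lists 63241 genes, 20601 of them with no symbol, and repeats no gene identifier. The TPM of each library sum to between 999999.03 and 1000000.89, as TPM do, so the values keep no sequencing depth and no counting interval was computed. The setting for strand in the authors' quantification is not given either, so antisense and overlapping genes are uncertain, as are genes that share reads with pseudogenes, read-through transcripts or close copies. Pairs of libraries with identical values numbered 0.

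The planned test for count data was not used, because the deposited unit is TPM. Values were analysed as log2(TPM + 1), so fold changes of low genes are understated. Genes with at least 1 TPM in at least 3 libraries were kept (14718 genes). A linear model with 1 coefficient per plasmid was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom and empirical Bayes moderation that follows mean expression. Each comparison was coded as the first group minus the second. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values of genes come from this limma model throughout. The 4 groups were compared together with limma's F test. MSX1 and PRMT1 were also compared with exact two-sided permutation tests, for which 3 libraries against 3 cannot give a p under 0.1. Nothing in the labels says that libraries of one group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

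Gene lists, the rule for naming genes, the tests and most alternatives were fixed before the data were examined. The 29 lists cover palate transcription factors, signalling pathways (BMP, WNT, hedgehog, TGF-beta, FGF and ERK), immediate early genes, interferon, NF-kB, heat shock, unfolded protein, p53 and hypoxia genes, G1/S and G2/M genes, histones, arginine methyltransferases, osteogenic, chondrogenic, matrix and cholesterol genes, ribosomal proteins, mitochondrially encoded genes, nuclear retained RNAs, and markers of epithelial, endothelial, immune, neural and muscle cells. Some genes belong to more than 1 list. The histone list holds replication-dependent and linker histones, and how well poly(A) selection catches their transcripts was not tested. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 29 lists within a comparison. They were tested again with an estimated correlation, under which no list was called in any comparison. Limma's fry, also planned, tests members against 0 and not against other genes. It called 9, 20 and 18 lists for R157S, R157K and R157F against WT. Between variants it called 25 for R157S against R157K, 1 for R157S against R157F and 25 for R157K against R157F. Unless stated, a list named as called passed camera at the preset correlation. These tests were run between variants only after the results against WT had been seen. The change of a list is given as the mean log2 change of its members minus that of all tested genes. Members called were counted over all genes tested and also adjusted over the list alone.

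Genes named in the text are MSX1 and PRMT1, the 8 higher and 8 lower called genes with the largest change in each variant against WT (5 and 5 between variants) that have a symbol, a mean of at least 2 TPM and no overlap between the groups, up to 4 called members of each list with the lowest adjusted p, and the 6 genes with the lowest p of the 4-group test. Many of the largest changes belonged to pseudogenes and read-through or antisense transcripts, so the size rule was also applied to protein-coding genes alone, a choice made after the values were seen. A few genes that the rule names are not reported here, though they stay in the counts of genes and the list tests. In comparisons between variants, list members named against WT are given as levels.

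Transcript GC content, length and coordinates were taken from GENCODE 29 (GRCh38), which may not be the authors' annotation, using the principal transcript where one is marked and otherwise the longest. A GENCODE transcript was found for 58174 genes (92.0%), and 96.6% of the tested genes had both values. As an alternative added after the data were seen, the trend of each library's log2 deviations on GC content and length (splines with 5 degrees of freedom) was removed and the model refitted on 14220 genes. The other alternatives were median-ratio scaling of libraries, limma without the mean trend, no filter and a filter of 5 TPM, the replicate number as a block, a model of only the compared groups, MSX1 left out, a pseudocount of 0.1, a minimum log2 change of 1, an estimated correlation for lists, and each library left out in turn.

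The labels carry a batch tag that equals the replicate number, so by the labels the numbers pair the libraries across groups. In the data, the deviations from the group means of libraries with the same number had a mean correlation across genes of 0.0035 (18 pairs, from -0.13 to 0.39, with 2 above 0.1), against -0.0011 for different numbers (36 pairs). The replicate block gave log2 0.58 for MSX1 in R157K against WT, the value of the model without it, and moved its adjusted p from 0.13 to 0.040.

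Simulated data were made from each gene's mean over the 12 libraries and its SD within groups, with changes added to the R157S columns. Each gene had the same SD in all 4 groups there. In the real libraries the SD of log2 differences between 2 libraries of a group was 0.35 to 0.59 with WT. With R157F it was 0.34 to 0.37. The limma model was tested on R157S against WT in the simulated data, so its rates need not hold where groups differ in spread. In 14718 genes it recovered 22.4% of genes changed by 0.5 on the log2 scale, 68.7% of those changed by 1 and 98.5% of those changed by 2, with 10 false calls (7.35% of calls). When a GC trend was added to 1 group, 927 calls were false, and 7 were after the trend was removed (14220 genes). The added trend was linear in the same GC values that the removal fitted. How fully the removal clears the trends of the real libraries was therefore not measured. In a simulation of the list test, 0 of 29 lists were called when no list was shifted, and 1 when 1 list was. Noise there was independent between genes, so false list calls from correlated genes were not measured. Comparisons that share the WT libraries were set beside 100 simulated draws with no effect. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, biopython 1.88 and matplotlib 3.10.9.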

Results

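Gene expression was measured in HEPM cells, a human line of embryonic palatal mesenchyme, 6 h after transfection with a plasmid for MSX1, a homeobox transcription factor of the developing palate and teeth. The protein was wild type (WT) or had a single arginine changed to serine (R157S), lysine (R157K) or phenylalanine (R157F). Each plasmid had 3 libraries, 12 in all, and WT MSX1 served as the reference because cells without an MSX1 plasmid were not analysed here. The series title names methylation of MSX1 by PRMT1, a protein arginine methyltransferase, and condensate formation by the methylated protein, and the comparisons ask which transcripts differ once that arginine is replaced. MSX1 (ENSG00000163132) lies on chromosome 4 at 4859666 to 4863936, plus strand, of GRCh38 as annotated by GENCODE 29. It has 2 coding exons, from 4859666 to 4860368 and from 4862701 to 4863936, and encodes 303 amino acids. The codon of the changed arginine is split by the intron, with its first base at 4860368 in exon 1 and the others at 4862701 and 4862702 in exon 2.

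Values were TPM, which keep no read depth, so the depth of each library is unknown. Libraries had 20954 to 22295 genes above 0 and 13541 to 14016 genes with at least 1 TPM. Mitochondrially encoded genes took 7.96% ± 1.83 (SD, n = 3) of the total with WT, 6.25% ± 0.117 with R157S, 6.70% ± 0.546 with R157K and 5.45% ± 0.143 with R157F, and the highest share was 9.96% in WT replicate 2. Ribosomal protein genes took 5.55% ± 0.858 with WT, 6.59% ± 0.143 with R157S, 12.5% ± 1.27 with R157K and 7.78% ± 0.189 with R157F. Below, values after ± are SDs over the 3 libraries of a group, changes are on the log2(TPM + 1) scale, and adjusted p-values of genes are limma's.

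MSX1 transcript, from the plasmid and the endogenous gene together, was at 337 ± 111 TPM with WT, 451 ± 168 with R157S, 500 ± 146 with R157K and 872 ± 213 with R157F. It rose with R157F by 1.39 (SE 0.32, adjusted p = 0.00288, exact permutation p = 0.1, the smallest that 3 against 3 can give). The changes of 0.41 with R157S (adjusted p = 0.335, exact permutation p = 0.5) and 0.58 with R157K (adjusted p = 0.13, exact permutation p = 0.3) did not pass the test. The R157K difference passed after median-ratio scaling (1.01, adjusted p = 0.012), with the replicate block (0.58, adjusted p = 0.040) and without R157K replicate 2 (0.84, adjusted p = 0.041). Of the fits with 1 library left out, it was smallest without WT replicate 2 and did not pass there. Once trends on GC content and length were removed, it was 0.15 (adjusted p = 0.669) and the R157S difference 0.044 (adjusted p = 0.936). The R157S difference was also 0.13 without R157S replicate 1 (adjusted p = 0.789). It was smaller without WT replicate 2 and larger without WT replicate 3, and passed in neither. The R157F difference was 0.81 with these trends removed (adjusted p = 0.038) and 0.70 with WT replicate 2 also left out (adjusted p = 0.12). Between variants, MSX1 differed by -0.98 for R157S against R157F (adjusted p = 0.083) and -0.82 for R157K against R157F (adjusted p = 0.069), and with the replicate block these passed (adjusted p = 0.041 and 0.021). MSX1 took between 0.0224% and 0.101% of the total of a library.

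PRMT1 was at 107 ± 27.0 TPM with WT, 137 ± 1.05 with R157S, 192 ± 12.9 with R157K and 182 ± 8.85 with R157F. It rose with R157K by 0.88 (SE 0.15, adjusted p = 0.000289) and with R157F by 0.80 (adjusted p = 0.00111), and its change of 0.39 with R157S did not pass (adjusted p = 0.0778). Each of these 3 differences had an exact permutation p of 0.1. After removal of the GC and length trends they were 0.32 with R157K and 0.23 with R157F, both past the threshold, and 0.04 with R157S. PRMT1 was lower with R157S than with R157K (log2 -0.48, adjusted p = 0.0195), while R157K and R157F differed by 0.08 (adjusted p = 0.716).

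**Figure D1:**
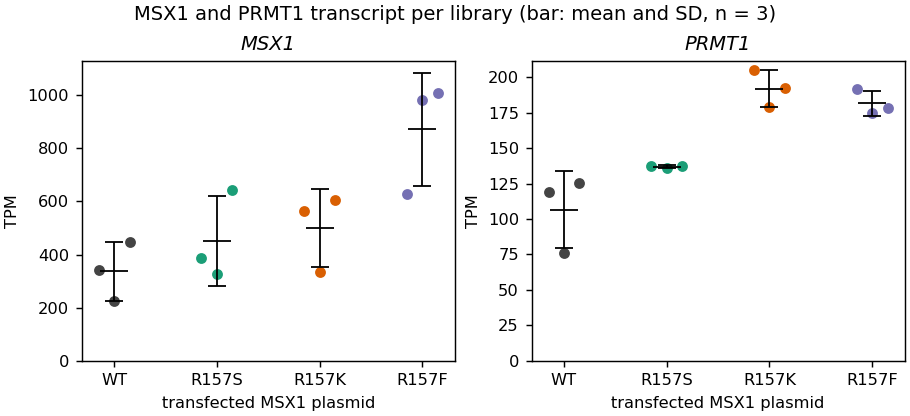
TPM of MSX1 and PRMT1 in each of the 12 libraries by plasmid, with the mean and SD of each group of 3. MSX1 ran from 224 to 1007 TPM and was highest on average with R157F, while mean PRMT1 was lowest with WT.

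Among the 4 plasmids together, 10413 of 14718 tested genes differed (limma F test), and 5971 of 14220 did after removal of the GC and length trends. CCNY, a membrane-bound cyclin, was at 75 ± 5.83 TPM with WT, 77.5 ± 2.16 with R157S, 18.4 ± 0.956 with R157K and 46.8 ± 3.45 with R157F. SOAT1, which esterifies cholesterol, fell from 126 ± 18.5 with WT to 80.0 ± 5.69, 20.8 ± 1.21 and 35.1 ± 4.12 with R157S, R157K and R157F. BZW1, a regulator of translation initiation, went from 892 ± 62.3 to 540 ± 18.8, 210 ± 26.1 and 404 ± 14.4 TPM. Each had an adjusted p of 8.51e-07, as had the other 3 genes of the 6 with the lowest p, which have no symbol.

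Against WT, 1119 genes were higher and 1883 lower with R157S, 2553 higher and 6806 lower with R157K, and 3596 higher and 4975 lower with R157F. Between variants, R157S had 6209 genes higher and 1162 lower than R157K, and 635 higher and 163 lower than R157F, and R157K had 486 higher and 3884 lower than R157F. TPM are shares of a total, and ribosomal protein genes took more of it with R157K. How much of the shifts below this accounts for was not measured. Median-ratio scaling moved the median of all genes by 0.36 for R157K against WT, 0.10 for R157F against WT, 0.03 for R157S against WT, -0.33 for R157S against R157K, -0.07 for R157S against R157F and 0.27 for R157K against R157F. The share of calls that were higher was 37.3%, 27.3% and 42.0% for R157S, R157K and R157F against WT, and 51.6%, 51.8% and 52.2% after this scaling. Between variants it was 84.2%, 79.6% and 11.1% for R157S against R157K, R157S against R157F and R157K against R157F, and 43.9%, 46.9% and 66.9% after scaling. For this reason changes of genes other than MSX1 and PRMT1 are given below relative to the all-gene median where R157K or R157F is compared with WT and where R157K is compared with another variant, while the test itself is against 0. Relative to that median the MSX1 difference was 0.91 for R157K and 1.48 for R157F against WT and -0.55 for R157K against R157F, and that of PRMT1 was 1.21, 0.88 and 0.35. For R157S against R157K they were -0.50 for MSX1 and -0.82 for PRMT1.

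**Figure D2:**
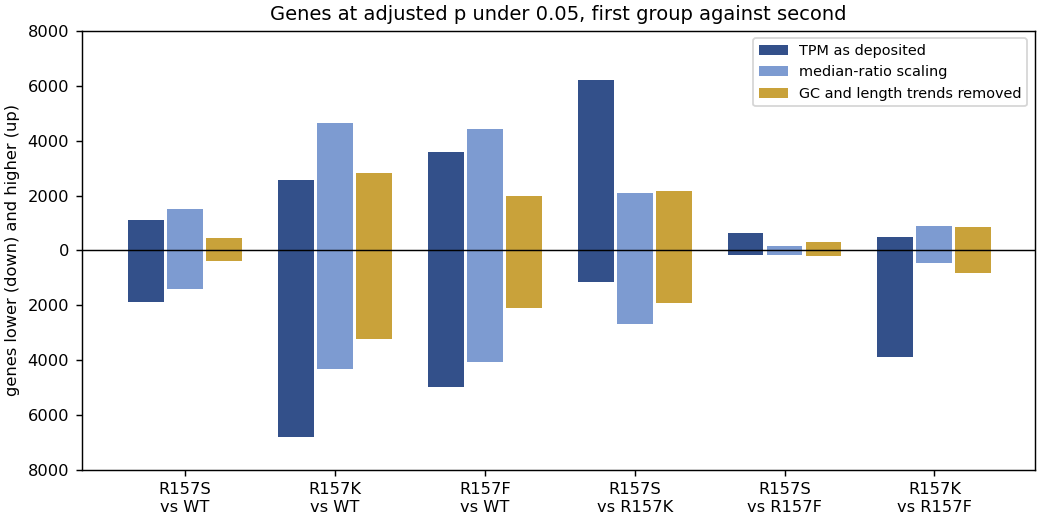
Number of genes called higher and lower in each comparison, for TPM as deposited, after median-ratio scaling and after removal of the GC and length trends. For R157K against WT the lower calls numbered 6806, 4340 and 3222 in these 3 settings, and the higher calls 2553, 4659 and 2831.

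Changes against WT followed the GC content of transcripts. Across 14220 genes, which are not independent replicates, Spearman's rho between the log2 change and GC content was 0.76 with R157S, 0.72 with R157K and 0.81 with R157F, and that with transcript length was -0.20, -0.41 and -0.26. In the 1422 genes lowest in GC content (27.8% to 38.8%) the median change was -0.52, -1.10 and -0.84. In the 1422 genes highest in GC content (61.9% to 75.6%) it was 0.47, 0.69 and 0.85. WT replicate 2 differed from WT replicate 3 along GC content as well (rho 0.75 for the difference between these libraries), and R157K replicate 1 from R157K replicate 2 (rho -0.62). Values after removal of these trends are given where the removal ended the call of a list, and for some of the genes named by rule.

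**Figure D3:**
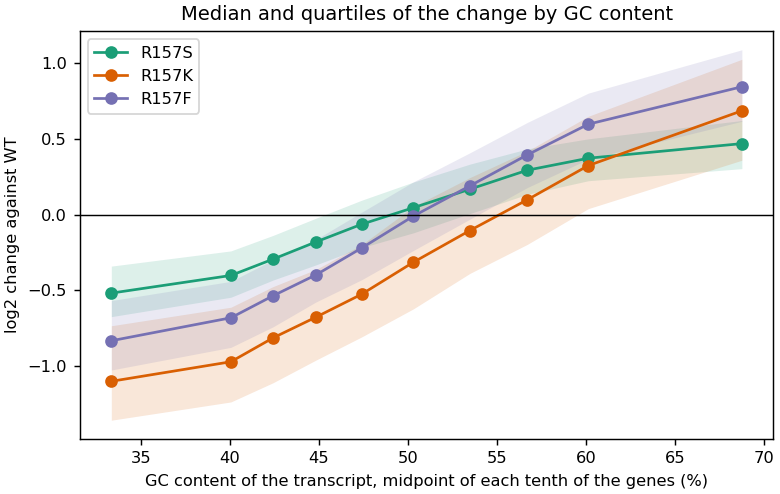
Median log2 change against WT (line) and quartiles (band) in 10 groups of 1422 genes by the GC content of the transcript in percent, for the 3 variants. All 3 lines rise with GC content, with R157K from -1.10 in the lowest group to 0.69 in the highest.

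With R157S, collagen and other matrix genes were higher than with WT and mitotic genes were lower. COL1A1 and COL3A1, which encode fibrillar collagens, rose from 558 ± 21.7 to 1230 ± 113 TPM (log2 1.14, SE 0.11) and from 181 ± 25.3 to 392 ± 36.2 TPM (log2 1.11, SE 0.11). SPARC, a collagen-binding matrix protein, rose by 0.49, whereas the collagenase gene MMP1 fell by 0.71 and the stromelysin gene MMP3 went from 28.2 ± 3.54 to 5.84 ± 2.16 TPM (log2 -2.13, SE 0.27). Of 38 tested matrix genes 16 rose and 4 fell (19 and 6 adjusted over the list alone), with a list mean 0.24 above that of all genes (camera adjusted p = 0.000524, and adjusted p = 0.478 with an estimated correlation). Of 38 G2/M genes 22 fell and 1 rose (26 and 1 adjusted over the list alone), with a list mean of -0.41 (camera adjusted p = 1.92e-07, and adjusted p = 0.42 with an estimated correlation). Among these were the cyclin gene CCNA2 (-0.69), the spindle genes DLGAP5 (-0.75) and NDC80 (-0.73) and the checkpoint kinase gene BUB1 (-0.58). After trend removal 6 G2/M genes were lower and 0 higher (camera adjusted p = 3.67e-08).

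Of 34 palate transcription factor genes 8 rose and 2 fell with R157S (11 and 3 adjusted over the list alone, mean 0.30, camera adjusted p = 0.000996, and adjusted p = 0.527 with an estimated correlation). TWIST1, a regulator of cranial mesenchyme, rose from 33.3 ± 3.31 to 60.6 ± 8.86 TPM (log2 0.84, SE 0.16), SIM2 and FOXF2 rose by 0.93 and 0.63, and ZEB1 fell by 0.56. Of 24 immediate early genes 6 rose and 1 fell (8 and 1 adjusted over the list alone, mean 0.33, camera adjusted p = 0.00213, and adjusted p = 0.527 with an estimated correlation). Among these were EGR1 (25.8 ± 2.25 to 53.4 ± 1.32 TPM, log2 1.02) and JUNB (0.99). This list was no longer called once the GC and length trends were removed (adjusted p = 0.165). Of 25 TGF-beta genes 8 rose and 2 fell (11 and 4 adjusted over the list alone, mean 0.20, camera adjusted p = 0.0102, and adjusted p = 0.478 with an estimated correlation). TGFBI rose by 0.71, THBS1 by 0.62, CCN2 by 0.53 and ACTA2 by 0.58. Of 9 osteogenic genes 5 rose and 0 fell (5 and 0 adjusted over the list alone, mean 0.39, camera adjusted p = 0.00514, and adjusted p = 0.317 with an estimated correlation). Among these were COL1A1, COL1A2 (0.61) and SPARC, which also belong to the matrix list.

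With R157S, 6 further lists were called. Limma's fry did not call the palate transcription factor (adjusted p = 0.0513), immediate early (0.0839), histone (0.0513) and ribosomal protein (0.142) lists with R157S. Of 40 ribosomal protein genes 6 rose and 0 fell (17 and 2 adjusted over the list alone, mean 0.28, camera adjusted p = 0.000145, and adjusted p = 0.527 with an estimated correlation). Of 17 histone genes 2 rose (2 adjusted over the list alone, mean 0.48, camera adjusted p = 0.00794, and adjusted p = 0.527 with an estimated correlation). H2AC6 rose by 0.78. Without WT replicate 2 the list missed the threshold (mean 0.23, adjusted p = 0.055), as it did with the trends removed as well (mean 0.19, adjusted p = 0.221). Of 7 muscle marker genes 3 rose (4 adjusted over the list alone, mean 0.44, camera adjusted p = 0.00988, and adjusted p = 0.317 with an estimated correlation). TAGLN (0.55) and LMOD1 (0.89) were among them, and the list's call ended after trend removal (adjusted p = 0.0735). Of 23 cholesterol synthesis genes 11 fell and 0 rose (12 and 1 adjusted over the list alone, mean -0.18, camera adjusted p = 0.0488, and adjusted p = 0.317 with an estimated correlation). Among these were IDI1 (-0.78) and HMGCS1 (-0.65). Of 12 immune cell markers only CD74 and CD68 were expressed enough to be tested, and both rose, by 1.00 and 0.73 (2 adjusted over the list alone, mean 0.87, camera adjusted p = 0.0304, and adjusted p = 0.478 with an estimated correlation). Of 9 hedgehog genes 1 rose, PTCH1 (0.82), and 0 adjusted over the list alone (mean 0.35, camera adjusted p = 0.0488, and adjusted p = 0.478 with an estimated correlation). With the replicate block the hedgehog (0.35, adjusted p = 0.062) and cholesterol (-0.18, adjusted p = 0.062) lists missed the threshold, as did PTCH1 and CD68 (adjusted p = 0.0587 and 0.0620). After trend removal the hedgehog list's mean was 0.10 (adjusted p = 0.551). It also missed the threshold after median-ratio scaling (adjusted p = 0.055), with a pseudocount of 0.1 (0.47, adjusted p = 0.0512) and without WT replicate 1, WT replicate 3 or R157S replicate 3 (adjusted p = 0.124, 0.0951 and 0.0764). The cholesterol list missed it after that scaling (adjusted p = 0.0745) and without WT replicate 1, WT replicate 3 or R157S replicate 1 (adjusted p = 0.0869, 0.127 and 0.0527).

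The largest R157S increases among protein-coding genes included AQP3, a water and glycerol channel (7.36 ± 0.386 to 22.8 ± 4.32 TPM, log2 1.49, SE 0.16), the neurotrophin receptor NGFR (1.46), TSPAN11 (1.33), the extracellular superoxide dismutase SOD3 (1.30) and DOK1, an adaptor of tyrosine kinases (48.9 ± 12 to 118 ± 5.54 TPM, log2 1.28). The largest decreases included, beside MMP3, SMCO4 (-1.57), the decoy receptor IL13RA2 (-1.52), STEAP1 (-1.41), the alarmin IL33 (59.0 ± 11.1 to 24.4 ± 10.3 TPM, log2 -1.30) and ESM1 (-1.23). After trend removal 5 palate transcription factor, 4 TGF-beta, 2 immediate early and 2 ribosomal protein genes were higher and 6 cholesterol genes lower, while matrix genes had 15 higher and 2 lower. In this setting FOXF2 (0.20), ZEB1 (-0.17), DLGAP5 (-0.30), NDC80 (-0.35), TAGLN (0.29), PTCH1 (0.73) and CD68 (0.48) no longer passed. Of the genes named by rule only AQP3, MMP3, EGR1 and COL1A1 passed with only these 2 groups in the model. In all 3002 genes passed, and 43.6% of tested genes had no overlap between the groups, against a chance of 10% for a single gene. Genes that vary together also separate together, so this share is not a test. The count was 9 with only these 2 groups in the model, 590 without the filter, 854 after trend removal and 125 with a change of at least 1. It was 39 without R157S replicate 2, 133 without replicate 3 and 1686 without replicate 1, and 667, 879 and 5761 without WT replicates 1, 2 and 3.

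**Figure D4:**
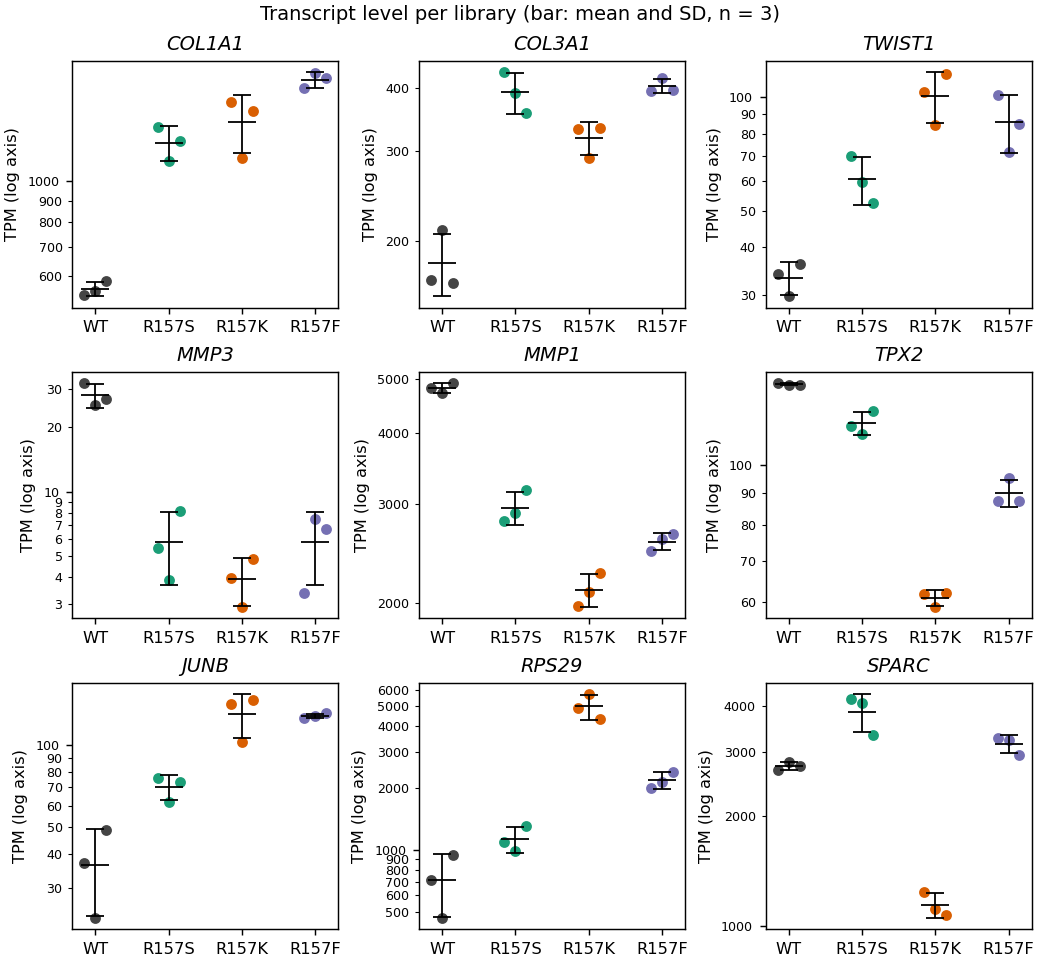
TPM per library, on a log axis, of 9 genes named in the text, with the mean and SD of each group of 3. COL1A1 and TWIST1 lay above the WT libraries in all variant libraries and MMP3 below them, while SPARC was above WT with R157S (3863 TPM on average) and below it with R157K (1142 TPM).

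With R157K, ribosomal protein and histone genes were higher than with WT and mitotic and FGF pathway genes were lower. Of 40 ribosomal protein genes 32 rose and 5 fell (32 and 5 adjusted over the list alone), with a list mean 1.17 above that of all genes (camera adjusted p = 3.82e-15, and adjusted p = 0.74 with an estimated correlation). RPLP2 rose from 549 ± 64.7 to 1563 ± 159 TPM and RPS20 from 805 ± 71.3 to 2098 ± 303 TPM (1.85 and 1.72 relative to the all-gene median, SE 0.10 each). The short ribosomal transcripts RPS29 (710 ± 241 to 4982 ± 708 TPM, relative change 3.2) and RPS21 (324 ± 68.9 to 2049 ± 231 TPM, 3.01) were among the largest increases. Of 17 histone genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, mean 1.10, camera adjusted p = 0.000174, and adjusted p = 0.74 with an estimated correlation). Among these were H2BC12 (1.91) and H2AC6 (1.48). With the trends removed and WT replicate 2 also left out, the histone list missed the threshold (mean 0.41, adjusted p = 0.0731). Whether poly(A) selection caught histone transcripts alike in all groups was not tested.

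Of 38 G2/M genes 32 fell and 2 rose with R157K (32 and 3 adjusted over the list alone, mean -0.60, camera adjusted p = 0.000465, and adjusted p = 0.74 with an estimated correlation). TPX2, a spindle assembly factor, fell from 135 ± 0.552 to 61.1 ± 1.80 TPM (relative change -0.79), and the cytokinesis genes KIF23 and PRC1 fell by 1.18 and 0.88 relative to the median. After trend removal 21 G2/M genes were lower and 3 higher. Of 20 genes of the FGF and ERK pathway 15 fell and 1 rose (15 and 1 adjusted over the list alone, mean -0.46, camera adjusted p = 0.0343, and adjusted p = 0.74 with an estimated correlation). Among these were the feedback phosphatase DUSP6 (-0.81), FGF5 (-1.03) and FLRT3 (-1.37). Of 24 immediate early genes 9 rose and 3 fell (9 and 3 adjusted over the list alone, mean 0.57, camera adjusted p = 0.0144, and adjusted p = 0.92 with an estimated correlation). JUNB, IER5 and IER2 rose by 2.20, 1.73 and 1.68 relative to the median. The FGF and immediate early lists were not called after trend removal (adjusted p = 0.111 and 0.137, with 2 FGF genes higher and 7 lower and 9 immediate early genes higher and 2 lower), nor the FGF list after median-ratio scaling (adjusted p = 0.068), without WT replicate 3 (adjusted p = 0.0605) or without R157K replicate 2 (adjusted p = 0.0647).

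Matrix genes went both ways with R157K, with 11 of 38 higher and 23 lower (11 and 24 adjusted over the list alone, list not called, camera adjusted p = 0.988), and after trend removal 13 were higher and 10 lower. COL1A1 rose from 558 ± 21.7 to 1377 ± 212 TPM (relative change 1.63), whereas SPARC fell from 2742 ± 72.0 to 1142 ± 88.5 TPM (-0.93) and MMP1 fell (-0.85). Among 34 palate transcription factors 9 rose and 10 fell (9 and 10 adjusted over the list alone, list not called, camera adjusted p = 0.0843), and after trend removal 10 were higher and 4 lower. TWIST1 rose by 1.90 and PRRX1, a mesenchymal homeobox gene, fell by 1.07, relative to the median. Mitochondrially encoded genes were 10 of 15 lower and 1 higher (10 and 1 adjusted over the list alone, list not called, camera adjusted p = 0.371), and after trend removal 7 were lower and 2 higher. The higher one, MT-ND3, rose by 2.15 and MT-ND4 fell by 0.91, relative to the median. TGF-beta (1 of 25 higher and 12 lower, the same adjusted over the list alone), osteogenic (3 of 9 higher and 5 lower, the same) and cholesterol genes (4 of 23 higher and 15 lower, 5 and 16 adjusted over the list alone) were not called as lists either (camera adjusted p = 0.773, 0.834 and 0.425). After trend removal they had 5 higher and 3 lower, 4 and 1, and 2 and 11, and were not called (adjusted p = 0.927, 0.221 and 0.093).

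Other large R157K increases were C4orf48 (10.5 ± 6.90 to 97.7 ± 3.8 TPM, relative change 3.63), the ATP synthase subunit ATP5ME (183 ± 67.1 to 1176 ± 23.3 TPM, 3.10) and MTLN, a mitochondrial microprotein (3.01). The largest decreases in protein-coding genes were PLEKHA3 (33.5 ± 0.664 to 3.33 ± 0.236 TPM, -2.66), the nuclear matrix gene MATR3 (-2.48), MMP3 (-2.25), SOAT1 (-2.19) and the selenoprotein SELENOT (-2.13). Beyond these, the largest changes by rule included pseudogenes, whose reads can be shared with their parent genes, such as PSMC1P1, listed at 0 in the WT libraries and at 76.4, 113 and 74.5 TPM with R157K. In all 9359 genes passed, and 63.5% of tested genes had no overlap between the groups, against a chance of 10% for a single gene. As genes vary together, this share is not a test either. The count was 6053 after trend removal, where 4123 genes kept their direction and 399 were called in the opposite one, and 3586 with a change of at least 1.

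With R157F, immediate early, histone, ribosomal protein and palate transcription factor genes were higher than with WT, and mitotic and mitochondrially encoded genes were lower. Each of these lists had an adjusted p = 0.586 with an estimated correlation, as had the matrix list. Of 24 immediate early genes 14 rose and 2 fell (16 and 2 adjusted over the list alone, mean 0.67, camera adjusted p = 6.24e-05). JUNB rose from 36.3 ± 12.8 to 128 ± 2.54 TPM (relative change 1.94, SE 0.21), EGR1 by 1.19 and IER2 by 1.24. Of 17 histone genes 14 rose and 0 fell (14 and 0 adjusted over the list alone, mean 0.98, camera adjusted p = 0.000172), with H2BC12 at 1.60. Of 40 ribosomal protein genes 25 rose and 3 fell (25 and 3 adjusted over the list alone, mean 0.48, camera adjusted p = 3.91e-05), including RPS15 (1.73) and RPL13 (1.29).

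Of 34 palate transcription factor genes 17 rose and 3 fell with R157F (18 and 3 adjusted over the list alone, mean 0.47, camera adjusted p = 0.00157). TWIST1 rose from 33.3 ± 3.31 to 86.0 ± 15.1 TPM (relative change 1.42, SE 0.16) and TWIST2 from 72.2 ± 18.4 to 158 ± 7.36 TPM (1.24). Of 38 G2/M genes 29 fell and 3 rose (29 and 3 adjusted over the list alone, mean -0.52, camera adjusted p = 3.91e-05), with KIF23 at -0.80 and the mitotic kinase AURKA at -0.58. After trend removal 17 G2/M genes were lower and 2 higher, 8 histone genes higher, and 5 mitochondrially encoded genes lower and 1 higher. Of 15 mitochondrially encoded genes 12 fell and 1 rose (13 and 1 adjusted over the list alone, mean -0.44, camera adjusted p = 0.00441), among them MT-ND4 (-0.86) and MT-ATP6 (-0.71). Of 38 matrix genes 18 rose and 10 fell (20 and 10 adjusted over the list alone, mean 0.28, camera adjusted p = 0.0291, and 20 higher and 3 lower after trend removal), with COL1A1 (558 ± 21.7 to 1729 ± 71.6 TPM, relative change 1.71), COL3A1 (1.24) and the elastin gene ELN (1.53) higher and MMP1 lower (-0.82). The matrix list missed the threshold without WT replicate 3 (adjusted p = 0.0777) and without R157F replicate 1 (adjusted p = 0.0554). The TGF-beta (11 of 25 higher and 6 lower, the same adjusted over the list alone), osteogenic (4 of 9 higher and 0 lower, the same) and cholesterol (4 of 23 higher and 13 lower, the same) lists were not called with R157F (camera adjusted p = 0.128 each). After trend removal all 3 were called at the preset correlation, with 7 higher and 1 lower (adjusted p = 0.0141), 6 and 0 (adjusted p = 0.000217) and 0 and 13 (adjusted p = 0.000134).

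The largest R157F changes in protein-coding genes included CEBPD, an acute-phase transcription factor (5.77 ± 1.30 to 26 ± 0.847 TPM, relative change 2.10), and SOD3 (2.01) among increases, and MMP3 (-2.06), SELENOT (-1.99) and SOAT1 (-1.73) among decreases. In all 8571 genes passed, and 66.3% of tested genes had no overlap between the groups, against a chance of 10% for a single gene. As genes vary together, this share is again not a test. The count was 4091 after trend removal, where 2786 genes kept their direction and 144 were called in the opposite one, and 1642 with a change of at least 1.

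**Figure D5:**
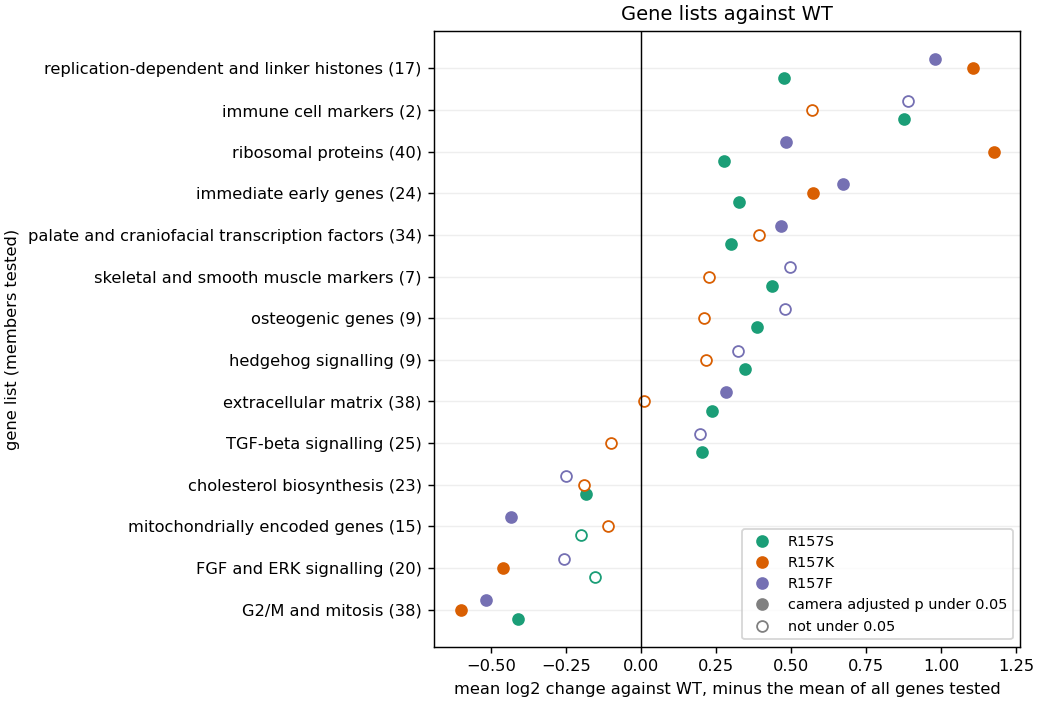
Mean log2 change of list members minus that of all tested genes, for the 14 lists called in at least 1 of the 3 variants against WT, with filled points where the camera adjusted p was under 0.05. G2/M genes lay at -0.41, -0.60 and -0.52 and ribosomal proteins at 0.28, 1.17 and 0.48 for R157S, R157K and R157F.

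Between R157S and R157K, ribosomal protein genes were the most separated list, with 29 of 40 lower and 4 higher with R157S (30 and 4 adjusted over the list alone, mean -0.90, camera adjusted p = 2.94e-20, and adjusted p = 0.847 with an estimated correlation). RPS29 was at 1132 ± 163 TPM with R157S and 4982 ± 708 with R157K (relative change -2.47, SE 0.21), and RPS21 and the short signalosome subunit COPS9 differed by -2.33 and -2.32. Higher with R157S were PLEKHA3 (18.8 ± 0.798 against 3.33 ± 0.236 TPM, relative change 1.86), MATR3 (1.81), CCNY (1.68) and TOX4 (1.56). Histones were lower with R157S (4 of 17 lower and 1 higher, 3 and 1 adjusted over the list alone, mean -0.63, camera adjusted p = 0.000474). TGF-beta genes (16 of 25 higher, 16 adjusted over the list alone, mean 0.30, camera adjusted p = 0.0342), FGF and ERK genes (16 of 20 higher, 16 adjusted over the list alone, mean 0.31, camera adjusted p = 0.0448) and G1/S genes (25 of 40 higher, 27 adjusted over the list alone, mean 0.19, camera adjusted p = 0.0448) were higher, with 0 lower in each. These 4 lists also had an adjusted p = 0.847 with an estimated correlation, and after trend removal none of them was called (adjusted p = 0.215, 0.0732, 0.528 and 0.452). In that setting 5 histone genes were lower and 0 higher, while 10 TGF-beta genes were higher and 1 lower, 7 FGF and ERK genes higher and 4 lower, and 7 G1/S genes higher and 2 lower. The mitochondrial list, not called before (10 of 15 higher and 3 lower, the same adjusted over the list alone, camera adjusted p = 0.763), was called after it (9 and 3, adjusted p = 0.0363). In all 7371 genes passed. There were 4785 after median-ratio scaling, 4078 after trend removal and 969 with a change of at least 1. The TGF-beta, FGF and G1/S lists also missed the threshold after median-ratio scaling (adjusted p = 0.0728, 0.222 and 0.484), without R157S replicate 1 (adjusted p = 0.0629, 0.0649 and 0.0803) and without R157K replicate 2 (adjusted p = 0.0953 each).

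Between R157S and R157F 798 genes passed. Immediate early genes were lower with R157S (5 of 24 lower and 0 higher, 7 and 0 adjusted over the list alone, mean -0.35, camera adjusted p = 6.53e-05, and adjusted p = 0.993 with an estimated correlation), with JUNB at 70.4 ± 7.42 against 128 ± 2.54 TPM. Histones (1 of 17 lower and 0 higher, 3 and 0 adjusted over the list alone, mean -0.50, camera adjusted p = 6.53e-05, and adjusted p = 0.993 with an estimated correlation) and ribosomal proteins (0 of 40 called, 0 adjusted over the list alone, mean -0.21, camera adjusted p = 0.000519, and again adjusted p = 0.993 with an estimated correlation) shifted the same way. At an unadjusted p under 0.05 (limma) 12 ribosomal protein genes were lower and 4 higher. Mitochondrially encoded genes were higher with R157S (7 of 15 higher and 1 lower, 11 and 1 adjusted over the list alone, mean 0.23, camera adjusted p = 0.00059, and adjusted p = 0.993 with an estimated correlation). After trend removal 3 mitochondrially encoded genes were higher and 1 lower, 4 immediate early genes lower, and 1 histone and 2 ribosomal protein genes lower. Of the largest protein-coding differences, ZNF737 (1.46), the iron-sulfur protein gene CISD2 (1.33), SRD5A3 (1.26), the ATP synthase subunit ATP5PB (218 ± 33.6 against 90.9 ± 10.1 TPM, 1.25) and POP4 (1.23) were higher. C4orf48 (-1.36), the transcription factor CEBPB (39.9 ± 5.65 against 94.1 ± 8.42 TPM, -1.22), ZACN (-1.16) and KLF16 (-1.12) were lower. After trend removal C4orf48 no longer passed (-0.59). The count was 493 after trend removal, 320 after median-ratio scaling, 344 without the filter, 438 without the mean trend, 85 with a change of at least 1 and 4615 with only these 2 groups in the model. It was 353, 61 and 46 without R157S replicates 1, 2 and 3, and 120, 120 and 33 without R157F replicates 1, 2 and 3.

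Between R157K and R157F, ribosomal protein genes were higher with R157K (25 of 40 higher and 1 lower, 26 and 3 adjusted over the list alone, mean 0.69, camera adjusted p = 1.75e-28, and adjusted p = 0.444 with an estimated correlation). The largest differences by rule included the ATP synthase subunit ATP5MK at 823 ± 100 against 311 ± 52.2 TPM (relative change 1.68, SE 0.15) and the complex I subunit NDUFA1 at 531 ± 82.6 against 212 ± 25.9 TPM (1.58). SPARC was at 1142 ± 88.5 TPM with R157K and 3155 ± 182 with R157F (relative change -1.20, SE 0.10), and RAB30 (-1.31), GRIP2 (-1.27) and PLCD3 (-1.17) were lower as well. Matrix genes (25 of 38 lower, 28 adjusted over the list alone, mean -0.28, camera adjusted p = 8.61e-05, and adjusted p = 0.46 with an estimated correlation), TGF-beta genes (16 of 25 lower, 19 adjusted over the list alone, mean -0.30, camera adjusted p = 0.00024, and adjusted p = 0.444 with an estimated correlation) and G1/S genes (20 of 40 lower, 26 adjusted over the list alone, mean -0.18, camera adjusted p = 0.00064, and adjusted p = 0.444 with an estimated correlation) were lower with R157K, with 0 higher in each. After trend removal 10 matrix, 5 TGF-beta and 3 G1/S genes were lower and 0 higher. FGF and ERK genes were lower (10 of 20, 11 adjusted over the list alone, mean -0.20, camera adjusted p = 0.0196, and adjusted p = 0.46 with an estimated correlation), and mitochondrially encoded genes went both ways (2 higher and 3 lower of 15, 2 and 4 adjusted over the list alone, mean 0.32, camera adjusted p = 0.0425, and adjusted p = 0.869 with an estimated correlation). Neither of these 2 lists was called after trend removal (adjusted p = 0.565 for both, with 1 FGF gene higher and 3 lower and 2 mitochondrial genes higher and 4 lower), and the FGF list was not called after median-ratio scaling (adjusted p = 0.117). The mitochondrial list was not called with the replicate block (0.32, adjusted p = 0.063) or without R157K replicate 2 (adjusted p = 0.474), R157F replicate 1 (adjusted p = 0.0634) or R157F replicate 3 (adjusted p = 0.114). In all 4370 genes passed. There were 1340 after median-ratio scaling, 1663 after trend removal, 193 with a change of at least 1 and 2842 without R157K replicate 2. There were 2433 and 2769 without R157F replicates 1 and 2.

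The 3 variants shared many calls against WT. R157S and R157F had 1009 genes higher and 1854 lower in both and 0 in opposite directions, where independent lists of these sizes would share 273 and 636. R157S and R157K shared 750 higher and 1842 lower (194 and 871 for independent lists), with 54 opposite, and R157K and R157F shared 2160 higher and 4739 lower (624 and 2301), with 37 opposite. After trend removal the pairs in this order shared 425 higher and 335 lower (65.8 and 56.8 for independent lists), 338 and 322 (93.4 and 87.2), and 1538 and 1723 (397 and 475). In all 3 variants 742 genes were higher and 1822 lower, 2564 in all. After median-ratio scaling 1299 were higher and 1284 lower, and after trend removal 332 and 305, or 637 in all. Simulated draws with no effect call almost no genes (highest shared count 0 in 100 draws), so they set no level for this count. Across genes, the correlation of log2 changes was 0.87 for R157S and R157F, 0.76 for R157S and R157K, and 0.88 for R157K and R157F, and the simulated medians, which come from the shared WT libraries alone, were 0.54, 0.53 and 0.54 (highest of 100 draws 0.827, 0.903 and 0.851). The covariances were 0.253, 0.263 and 0.482, against simulated values of 0.0301, 0.0286 and 0.0302, a difference of 0.223, 0.235 and 0.452. With the trends removed the correlations in this order were 0.729, 0.593 and 0.8010. The highest simulated values were then 0.886, 0.898 and 0.8014, so each correlation lay within its draws. The covariances then exceeded the simulated ones by 0.0736, 0.0788 and 0.170. The comparisons were not repeated with a different WT library for each variant, so part of the excess may come from the shared controls. The shared count was 34 without R157S replicate 2, 118 without R157S replicate 3 and 4818 without WT replicate 3. Of the 11066 genes called in any variant against WT, R157S had the smallest of the 3 changes in 75.7% and R157K the largest in 70.0%. Relative to the all-gene median of each comparison these shares were 74.5% and 59.7%. The genes were chosen by these same changes, 9359 of them called with R157K and 3002 with R157S. That choice itself favours R157K as the largest and R157S as the smallest.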

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

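The 4 settings that removed trends on GC content and length were chosen after the data were seen, as was the naming of protein-coding genes alone. The list tests, fixed for any comparison, were run between variants only once those against WT had been seen. The removal was first run with the longest transcript of each gene, and the principal transcript was adopted once its values had been seen. TPM keep no depth, so what depth limits could not be measured. Replicates left out leave groups of 2, which limma tests with the spread pooled over all groups. Of 432 results on genes named by rule, 219 kept their direction and their side of the threshold in every alternative, 203 lost their call in at least 1, 8 gained one in at least 1 and 29 turned sign in at least 1. The settings fixed beforehand, other than leaving out a library, kept 3183 values, ended 244 calls and made 8. Leaving out libraries kept 2205, ended 381, made 5 and moved 1. The removal settings kept 1182, ended 400, turned 74 and moved 2. For lists, the settings fixed beforehand kept 1257 values, ended 60 calls, made 26, moved 48 and turned 1, leaving out libraries kept 947, ended 20, made 22 and moved 55, and the removals kept 428, ended 37, made 23, moved 118 and turned 3. The list mean and the list test differed in sign for 15 of 174 list results, 0 of them called. Changes of genes in this part are as measured, not relative to the all-gene median. Unless stated, the cause of a difference was not tested.

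The genes differing among the 4 plasmids numbered 5971 with the trends removed, 6311 with the longest transcript, 5658 with the replicate block as well and 5572 with WT replicate 2 also left out. In the same order, R157S against WT gave 854, 961, 672 and 477 genes, and R157F against WT gave 4091, 4321, 3899 and 2895. R157K against WT gave 6053 with the trends removed, 5962 with the replicate block as well and 5399 with WT replicate 2 also left out. With the trends removed, with the longest transcript and with the replicate block as well, R157S against R157K gave 4078, 4219 and 3958, R157S against R157F 493, 491 and 325, and R157K against R157F 1663, 1802 and 1464. The genes called in all 3 variants numbered 637, 745, 513 and 351 in the order of the first sentence. The correlations of changes for R157S and R157K, R157S and R157F, and R157K and R157F were 0.593, 0.729 and 0.801 with the trends removed, with or without the replicate block. They were 0.601, 0.738 and 0.805 with the longest transcript, and 0.540, 0.669 and 0.781 with WT replicate 2 also left out. MSX1 with WT replicate 2 also left out differed by -0.064 in R157S and 0.70 in R157F against WT. For R157K against WT the lists called numbered 3 with the trends removed, 3 with the replicate block as well and 2 with WT replicate 2 also left out. For R157F against WT they numbered 11 in each of these 3 settings. For R157S against R157K they numbered 2 with the trends removed, 2 with the block as well and 3 with the longest transcript.

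Median-ratio scaling gave 4785 genes for R157S against R157K, 320 for R157S against R157F and 1340 for R157K against R157F, with 2 lists for R157S against R157K and 1.01 for MSX1 with R157K against WT. Libraries with R157K had factors of 0.769 to 0.859, against 1.00 to 1.12 in the others. A minimum log2 change of 1 left 125, 3586 and 1642 genes for R157S, R157K and R157F against WT, 969 for R157S against R157K, 85 for R157S against R157F and 193 for R157K against R157F, as a stricter threshold must leave fewer. Without the filter on low values R157S against WT gave 590 genes, R157S against R157F 344 and all 3 variants together 515, and 9 lists were called for R157K against WT, 9 for R157S against R157K and 17 for R157K against R157F. The correlations of changes, in the order given for the trends, were then 0.715, 0.832 and 0.852, and with a pseudocount of 0.1 they were 0.695, 0.792 and 0.845. The stricter filter called 2 lists for R157S against R157K. It ended the hedgehog (adjusted p = 0.106), cholesterol (adjusted p = 0.091) and muscle (adjusted p = 0.0557) calls for R157S against WT and the FGF calls for R157K against WT (adjusted p = 0.128) and R157F (adjusted p = 0.078). No filter ended the immune call for R157S against WT (adjusted p = 0.0735) and the mitochondrial call for R157K against R157F (adjusted p = 0.149). Without the mean trend R157S against R157F gave 438 genes. With only the compared groups in the model, R157S against WT gave 9 genes and R157S against R157F 4615. With an estimated correlation (limma's camera) 0 lists were called in each of the 6 comparisons, and at an unadjusted p under 0.05 there were 3, 0 and 1 for R157S, R157K and R157F against WT, 0 for R157S against R157K, 0 for R157S against R157F and 3 for R157K against R157F.

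The replicate block gave 0.58 for MSX1 with R157K against WT (adjusted p = 0.0396) and passed it, as it did MSX1 for R157S against R157F (-0.98, adjusted p = 0.0410) and R157K against R157F (-0.82, adjusted p = 0.0212), and TUG1 for R157S against WT (-0.36, adjusted p = 0.0471). It ended the calls of PTCH1 (0.82, adjusted p = 0.0587), PRMT3 (-0.50, adjusted p = 0.0510), PRMT6 (0.35, adjusted p = 0.0578), CD68 (0.73, adjusted p = 0.0620) and the hedgehog (0.35, adjusted p = 0.0622) and cholesterol (-0.18, adjusted p = 0.0622) lists for R157S against WT. It ended those of LMOD1 for R157K against WT (0.40, adjusted p = 0.0573), and of H4C12 (2.13, adjusted p = 0.0540), SMO (0.41, adjusted p = 0.0672) and SNHG14 (-0.39, adjusted p = 0.0562) for R157F against WT. Between variants it ended those of RN7SL2 (-1.81, adjusted p = 0.0516) and DNAJB14 (-1.13, adjusted p = 0.0552) for R157S against R157F and of the mitochondrial list for R157K against R157F (0.32, adjusted p = 0.0627). The block alone changed no other call of a named gene or list and moved no count of genes by over 1.5 times.

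Without 1 library at a time, R157S against WT gave 39 (without R157S replicate 2) to 5761 genes (without WT replicate 3), with 667 and 879 without WT replicates 1 and 2 and 1686 and 133 without R157S replicates 1 and 3. R157S against R157F gave 33 (without R157F replicate 3) to 353 (without R157S replicate 1), with 61 and 46 without R157S replicates 2 and 3 and 120 without R157F replicate 1 or 2. R157K against R157F gave 2433 (without R157F replicate 1) to 3815 (without R157K replicate 3), with 2842 without R157K replicate 2 and 2769 without R157F replicate 2. The genes called in all 3 variants numbered 34 (without R157S replicate 2) to 4818 (without WT replicate 3), with 601 and 755 without WT replicates 1 and 2 and 1447 and 118 without R157S replicates 1 and 3. MSX1 with R157K against WT ranged from 0.31 (without WT replicate 2) to 0.84 (without R157K replicate 2, where it passed). The correlations ranged from 0.648 (without WT replicate 2) to 0.814 (without WT replicate 3) for R157S and R157K, 0.774 to 0.906 for R157S and R157F and 0.849 to 0.906 for R157K and R157F. The lists called for R157S against R157K ranged from 2 (without R157S replicate 1) to 7 (without R157S replicate 3). Within 1.5 times of the full set stayed the 4-plasmid test (9544 to 10781), R157K (8521 to 9525) and R157F (7159 to 8969) against WT, and R157S against R157K (6354 to 6802). Of 102 named genes called for R157S against WT, 13 kept the call without R157S replicate 2 and 26 without replicate 3, and 4 with only the 2 groups in the model.

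With the trends removed, with or without the replicate block, the sign turned for TWSG1 with R157S (0.072). With R157K it turned for ZEB2 (0.080), WNT16 (0.020), FZD4 (0.25), LTBP1 (0.015), FAS (0.047), OIP5-AS1 (0.33), MALAT1 (0.28), SNAP25 (0.035) and TUBB3 (-0.23), and with R157F for GLI2 (-0.049), SMO (-0.21), IFIT5 (0.033), COL9A2 (-0.25), KRT18 (-0.036), KRT7 (-0.12), TUBB3 (-0.044), DES (-0.12) and CNN1 (-0.14). With WT replicate 2 also left out it turned for TWSG1 with R157S (0.060), and with R157K for FZD4 (0.32), FAS (0.00090), MATN3 (0.069), HAPLN1 (0.11), SNHG14 (0.046), OIP5-AS1 (0.37), MALAT1 (0.46), KRT18 (-0.0078), SNAP25 (0.070) and TUBB3 (-0.25). In that setting it also turned with R157F for SMO (-0.11), COL9A2 (-0.066), OIP5-AS1 (0.016), SNHG14 (0.052), KRT18 (-0.071), TUBB3 (-0.066) and CNN1 (-0.17). With the longest transcript it turned for TWSG1 (0.032) and PRMT3 (0.038) with R157S, and with R157K for ZEB2 (0.074), FZD4 (0.21), PRMT3 (0.036), OIP5-AS1 (0.31), MALAT1 (0.26), SNAP25 (0.11) and TUBB3 (-0.20). There it also turned with R157F for FZD2 (-0.037), GLI2 (-0.061), SMO (-0.24), HSP90B1 (0.014), COL9A2 (-0.27), KRT7 (-0.16), TUBB3 (-0.0013), DES (-0.16) and CNN1 (-0.12). Of these, FZD4, OIP5-AS1 and TUBB3 with R157K were called in the opposite direction in all 4 settings. The mean of the mitochondrial list for R157S against R157K turned to 0.093 with the trends removed, with or without the replicate block, and 0.087 with the longest transcript. The mean of the list of unfolded protein genes for R157K against R157F turned to -0.11 without the filter. In both results the list test kept its direction. The test direction of the mitochondrial list for R157K against R157F turned from higher to lower with the trends removed, with the replicate block as well and with the longest transcript. It was not called there, and its mean stayed above that of all genes.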

Other observations

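The tests of GC content and length, of short transcripts and of MSX1 amount were chosen after the results were seen, and the regroupings of libraries before. HEPM cells in these libraries expressed interferon-stimulated genes at a high level. Of 45 genes on the interferon list 17 were among the 500 genes with the highest mean TPM and 41 had a mean of at least 100 TPM. The list was not called in any variant against WT (camera adjusted p = 0.124, 0.271 and 0.232 for R157S, R157K and R157F), and its members went both ways. With R157S 6 were higher and 17 lower (12 and 21 adjusted over the list alone), with R157K 8 and 28 (8 and 28) and with R157F 12 and 24 (12 and 24). After removal of the GC and length trends the counts were 0 and 5, 11 and 19, and 14 and 10, so the majority with R157F turned from lower to higher. The effector genes IFI6 and ISG15 were at 1974 ± 342 and 1048 ± 399 TPM with WT (SD, n = 3) and 4831 ± 190 and 3840 ± 117 TPM with R157K, both higher. The antiviral gene RSAD2 was lower, at 1228 ± 85.9 TPM with WT and 504 ± 36.9 TPM with R157K. Which part of the interferon level comes from transfection was not analysed here.

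The pathways of palate growth other than those described were not called against WT. Counts are given as higher and lower with R157S, R157K and R157F in turn, and then adjusted over the list alone. Of 24 BMP genes 3 and 4, 5 and 13, and 6 and 8 passed (4 and 5, 5 and 13, 7 and 8), with camera adjusted p = 0.703, 0.773 and 0.807. Of 22 WNT genes 4 and 2, 3 and 7, and 6 and 4 passed (4 and 3, 2 and 7, 6 and 4), with adjusted p = 0.294, 0.998 and 0.316. Of 40 G1/S genes 1 and 8, 2 and 26, and 9 and 19 passed (2 and 11, 3 and 26, 9 and 19), with adjusted p = 0.156, 0.0693 and 0.386. Of 14 arginine methyltransferase genes 1 and 1, 2 and 6, and 4 and 5 passed (1 and 1, 2 and 6, 6 and 5), with adjusted p = 0.41, 0.926 and 0.643. Of 6 chondrogenic genes 0 and 1, 1 and 4, and 1 and 0 passed (0 and 2, 1 and 4, 0 and 0), with adjusted p = 0.383, 0.988 and 0.92. Among stress lists, NF-kB (30 genes, 5 and 4, 8 and 10, 11 and 6 passed, and 6 and 4, 8 and 10, 11 and 6 adjusted over the list alone) had adjusted p = 0.294, 0.371 and 0.161. Heat shock (24 genes, 3 and 8, 7 and 14, 7 and 12, the same adjusted over the list alone) had adjusted p = 0.294, 0.773 and 0.546. The unfolded protein list (32 genes, 6 and 2, 7 and 16, 12 and 11, and 6 and 5, 8 and 16, 12 and 11 adjusted over the list alone) had adjusted p = 0.294, 0.773 and 0.511. The p53 list (28 genes, 3 and 3, 6 and 14, 8 and 12, and 3 and 3, 7 and 14, 8 and 12 adjusted over the list alone) had adjusted p = 0.844, 0.988 and 0.92. Hypoxia (21 genes, 2 and 3, 2 and 12, 3 and 7, the same adjusted over the list alone) had adjusted p = 0.355, 0.468 and 0.532. Nuclear retained RNAs (6 genes, 0 and 0, 0 and 4, 1 and 3, the same adjusted over the list alone) had adjusted p = 0.156, 0.661 and 0.506. Markers of epithelial (10 tested genes, 0 and 0, 4 and 1, 3 and 0), endothelial (5, 0 and 0, 1 and 1, 2 and 1) and neural cells (3, 0 and 0, 1 and 1, 1 and 0) gave the same counts adjusted over the list alone. Their lowest adjusted p in any variant were 0.0843, 0.53 and 0.41. These splits depended on the GC and length trends. With the trends removed, BMP genes were 2 and 0, 5 and 5, and 5 and 2, WNT genes 3 and 1, 4 and 4, and 5 and 2, and G1/S genes 0 and 1, 2 and 14, and 3 and 6. Arginine methyltransferase genes were 0 and 0, 4 and 3, and 4 and 2, and chondrogenic genes 0 and 2, 0 and 0, and 0 and 0. NF-kB genes were 5 and 2, 9 and 5, and 9 and 2, heat shock genes 1 and 1, 6 and 10, and 6 and 7, and unfolded protein genes 4 and 0, 10 and 5, and 7 and 4. The p53 genes were 1 and 1, 7 and 4, and 4 and 4, hypoxia genes 1 and 4, 3 and 10, and 3 and 8, and nuclear retained RNAs 0 and 0, 3 and 1, and 1 and 1. Epithelial markers were 0 and 1, 1 and 0, and 0 and 1, endothelial 0 and 0, 2 and 2, and 0 and 2, and neural 0 and 0, 0 and 1, and 0 and 0. Of the lists in this paragraph, G1/S was then called with R157S (camera adjusted p = 0.0185) and NF-kB with R157F (camera adjusted p = 0.0211).

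The changes against WT followed the GC content of transcripts. GC-dependent differences between libraries are a candidate explanation, since libraries of one plasmid also differed along GC content in 2 of 4 groups (WT and R157K), with a rho of up to 0.75 in size. As the whole source of the calls the trends, as computed from a single GENCODE transcript per gene, are argued against. After their removal 5971 genes differed among the 4 plasmids, while the highest count in other groupings of the libraries was 2073. The removal may be incomplete, since other transcripts of a gene may be expressed, and this count cannot exclude that. How much of the trend belongs to the plasmids stays open, since the labels give no control library to measure it in. A biological effect of the residue on transcripts by their GC content was not tested.

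Ribosomal protein transcripts were higher with R157K than with WT, by a median of 1.39 relative to all genes (interquartile range 0.85 to 1.72). With trends on GC content and length removed, the list's median was 0.83 (interquartile range 0.40 to 1.29). Then 33 of 40 genes were higher and 0 lower (camera adjusted p = 2.98e-15). This argues against the trends, as computed, as the whole source. Lengths were those of a single GENCODE transcript per gene, with quartiles of 817 and 2102 for the list. If the transcripts expressed are shorter, the removal took out too little for these genes, which was not tested. A gain of short transcripts of any kind may be part of the rise. By the same lengths, the 2156 other protein-coding transcripts of like length and GC content had a median of 0.44 (interquartile range -0.03 to 0.88). That lies between the bounds set for and against such a gain, so the size of this part stays open. An effect of the lysine on ribosomal protein genes stays open as well and was not tested otherwise.

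The first principal component (57.8% of the variance) ordered the libraries WT, R157S, R157F and R157K, and it kept that order with the trends removed (41.8%). If the amount of MSX1 transcript set this order, MSX1 would be higher with R157K than with R157F, but it differed by -0.82 (SE 0.32). The difference was -0.50 (SE 0.30) after median-ratio scaling and -0.66 (SE 0.26) with the trends removed, so the value after scaling lies within 2 standard errors of 0 and the amount of MSX1 could not be excluded. The identity of the changed residue stays open as an explanation and was not tested apart from the libraries that carry it.

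Among 100 groupings of the 12 libraries into 4 groups of 3, 1, the real one, called as many as 10413 genes (limma), and the highest other called 4972. After trend removal 1 of 100 called as many as 5971, with 2073 the highest other. This argues against a random division of these libraries for both counts. The regroupings cannot tell an effect of the plasmid from differences between the transfections or preparations of each group. For pairs of groups there are 10 splits of 6 libraries, too few for a share under 0.05. In each comparison 1 split, the real one, gave the real count. A split that mixes 2 groups moves the difference between them into the spread of the model. It then calls few genes whatever the cause of the difference, so the distance between the counts below is no support for them. R157S against WT gave 3002 genes with 2 the highest other, R157K against WT 9359 with 1, and R157F against WT 8571 with 1. R157S against R157K gave 7371 with 1, R157S against R157F 798 with 2, and R157K against R157F 4370 with 2. Among splits that part all 3 numbered pairs the highest others were 1, 0, 1, 1, 2 and 1 in this order.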
